A study of Mus musculus with 17 samples.

How the data were processed

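RNA was measured on Affymetrix Mouse Gene 2.0 ST arrays, 17 in all, from 9 cell populations isolated by flow cytometric sorting. Per the labels, the cells were pooled from mice that had been lethally irradiated and given marrow of TCF-1 GFP reporter donors. The labels also state that RNA was extracted with Trizol, amplified with the NuGEN Pico V2 kit and labelled with biotin. The values are log2 expression values per probe set, deposited by the authors as a table of 41345 probe sets for the 17 arrays, and the unit was read from the values themselves. Per the labels, the authors made them with Affymetrix Expression Console, whose version and algorithm (background correction, scaling and summary) are not given in the sources used here. The array medians of the deposited log2 values over genes lay between 4.45 and 4.62, and single values between 1.58 and 13.77. No filter on low values was seen in the table. The intensity files were not used here.

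Probe sets were named from the array annotation, which lists 25335 of them. Only the 23521 probe sets with 1 gene symbol were tested, 1814 with several symbols and 16010 with none were left out, and no symbol needed updating. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 22180 genes. Tcf7, which encodes TCF-1, has no probe set of its own in this annotation, so the part of the gene rule that put it first was not applied.

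A linear model with 1 mean per population was fitted to the deposited log2 values of all 17 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 5.33 prior degrees of freedom). Replicate numbers were not taken to pair samples across populations, so no block was fitted in the reported values. EILP has 1 array, which the model assumes to vary like the arrays of the other populations. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, separately in each of 10 comparisons, and the number that also changed at least 2-fold is given beside it. A fold change is a difference of log2 means with its standard error (SE) from the fit. Genes apart in EILP were those called in the same direction, with a log2 fold change of at least 1, against each of the 8 other populations. The arrays of 1 population were also compared with each other in the same way, with 7 residual degrees of freedom. Likeness between arrays was measured by Pearson correlation across genes and by principal components of the 2000 most variable genes, without a test. All tests were two-sided.

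Before the data were examined, 23 gene lists were fixed: stem and multipotent progenitor, lymphoid priming, B lineage, T lineage, Notch target, NK cell and cytotoxic, granulocyte and monocyte, megakaryocyte and erythroid, dendritic cell, cell division, DNA replication, immediate early and stress, and interferon response genes, innate lymphoid transcription factors, innate lymphoid receptors and surface proteins, lymphoid effector cytokines, and markers of macrophages, mature B and plasma cells, mature T cells, red cells, stroma and endothelium, and thymic epithelium, with sex-linked genes as a check of the pools. Members are counted by the test over all genes and again with p adjusted over the list alone. Each list was also compared with all other genes by camera, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, and the adjusted p of a list is over the 23 lists of its comparison. The test was made 230 times, and 109 list shifts were called with the preset and 72 with the estimated correlation. A list adjusted p given alone is with the preset correlation. The estimated one can be far larger, such as 0.00068 in place of 8.4e-35 for B lineage genes in EILP minus CLP. Named genes were also fixed by rule: the 10 largest changes in each direction for the 4 EILP comparisons and the 8 largest for the 6 others, among called genes with at least a 2-fold change and no overlap between the arrays compared. Genes apart in EILP and list members were named too. Predicted genes, small RNA genes, pseudogenes and antigen receptor gene segments were left out of the rule.

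The model was tested on simulated data of the same design, with 100 genes changed at each size among 22180. Every simulated array, EILP included, was given independent noise with the fitted spread of each gene. The numbers of false calls therefore cannot show how far the real EILP array varies. For EILP against CLP, 36% of genes with a log2 change of 1 and 92% with a change of 2 were recovered, with 5 false calls. For LMPP against HSC, 54% and 98% were recovered, with 12 false calls. The number of arrays limits the precision, and the median SE of a log2 fold change was 0.24 for EILP against a pair of arrays and 0.20 between pairs.

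The alternatives tried were centring each array on its median, quantile normalization, leaving out dim genes, the mean of a gene's probe sets, all probe sets of the table, a trended and robust variance prior, only the arrays of the 2 groups compared, replicate number as a covariate, leaving out each array in turn, and a 2-fold threshold. Alternatives added after seeing the data left out genes that follow the neutrophil transcripts, the NK or ETP arrays where they were not compared, or the arrays with or without Y-linked transcripts. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.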

Results

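Gene expression was measured in 9 sorted mouse cell populations, each on 2 arrays except the early innate lymphoid progenitor (EILP), which had 1. From bone marrow came hematopoietic stem cells (HSC), lymphoid-primed multipotent progenitors (LMPP), common myeloid progenitors (CMP) with and without Flt3 on their surface (flt3+ and flt3-), common lymphoid progenitors (CLP), EILP and natural killer cells (NK). From thymus came early thymic progenitors (ETP) and DN3 thymocytes, a later stage of T cell development. The cells were pooled from chimeric mice, and nothing in the labels says that replicates come from separate animals, so p-values measure only the spread between these samples. Array medians lay between 4.45 and 4.62 on the log2 scale, and the number of arrays limits the precision. In every comparison, the size of a change is uncertain where 1 side lies below the median of all values, 4.54. That holds for many of the largest changes. Tcf7, the gene of the reporter carried by the donor marrow, was not analysed here.

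Transcripts of the Y-linked genes Eif2s3y, Kdm5d and Uty were high in the 5 CLP, EILP and DN3 arrays, with means over the 3 genes from 7.03 to 7.66, and low in the other 12, from 3.03 to 3.38. Xist, which is transcribed from the inactive X chromosome, was at 11.24 to 11.81 in those 12 arrays, 8.97 to 9.44 in CLP and EILP, and 7.13 to 7.50 in DN3. Comparisons of EILP with CLP, LMPP with HSC, the CMP populations with each other and ETP with LMPP therefore lie within 1 side of this split. The 6 others cross it, and there the split and the population cannot be told apart. S100a8, which encodes a calcium-binding protein abundant in neutrophils, was at 11.95 to 12.50 in all 13 marrow arrays and at most at 6.67 in the 4 thymus arrays. Camp, the precursor of an antimicrobial peptide of neutrophil granules, was highest in EILP at 12.05 and CLP at 11.97, and lowest in DN3 at 3.52. Over the 13 marrow arrays, 394 genes followed the mean of the neutrophil genes Ltf, Camp and Ngp with a correlation above 0.8. This selection was made after seeing the data, and its share of the calls stands with each comparison. Ltf was itself highest in EILP at 11.65 and CLP at 11.44, with NK next at 10.23. Genes high in CLP and EILP for any reason can therefore be among the 394, so these shares do not measure neutrophil RNA.

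**Figure D1:**
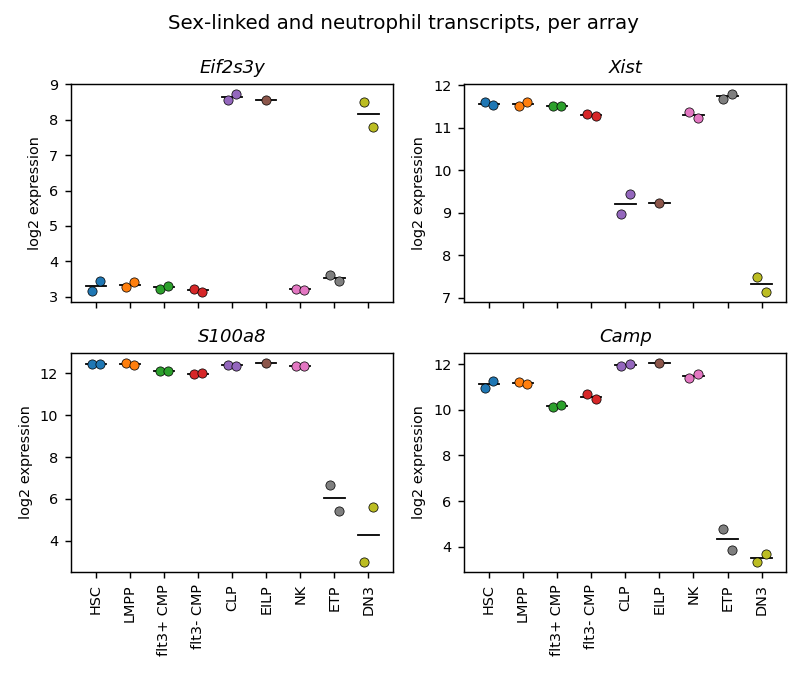
Log2 expression of Eif2s3y, Xist, S100a8 and Camp in each array by population, with points for arrays and a line for the mean of each population. Eif2s3y was high in the 5 CLP, EILP and DN3 arrays, and S100a8 lay between 11.95 and 12.50 in the 13 marrow arrays and at most at 6.67 in the 4 thymus arrays.

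The EILP array resembled CLP more than any other population. Its mean Pearson correlation across 22180 genes, which are not independent replicates, was 0.9797 with CLP, 0.9611 with LMPP, 0.9595 with flt3+ CMP, 0.9577 with HSC, 0.9568 with flt3- CMP, 0.9544 with NK, 0.9258 with ETP and 0.9158 with DN3. Replicates of 1 population correlated at 0.9734 (ETP) to 0.9901 (flt3- CMP). The value for EILP and CLP lay above those for replicates of NK (0.9767) and ETP only, and below that for replicates of CLP (0.9871). Other pairs of different populations were as alike, with 0.9798 for HSC and LMPP and 0.9827 for flt3+ and flt3- CMP. Over the 2000 most variable genes of the other arrays, the value for CLP was 0.9212 and the next highest was 0.7758 for flt3- CMP. EILP and CLP share high neutrophil transcripts and Y-linked transcripts. Without the 394 genes that follow the former and the sex-linked genes, left out after seeing the data, CLP stayed the highest at 0.9790, with flt3+ CMP next at 0.9693. Over the 2000 most variable of the remaining genes the values were 0.9071 and 0.8526, so the lead of CLP was smaller. The genes left out can include ones that CLP and EILP share for other reasons, so this drop cannot be put down to neutrophil RNA. Principal components 1, 2 and 3 held 39.5%, 20.5% and 12.5% of the variance. On the first pair EILP lay at -36.61 and 5.19, beside CLP at -34.24 and 6.26 and at -35.99 and 7.50. On component 3 it lay apart from CLP, at -10.09 against -19.20 and -18.52. There the flt3- CMP arrays, at -7.37 and -8.89, were nearer to it.

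**Figure D2:**
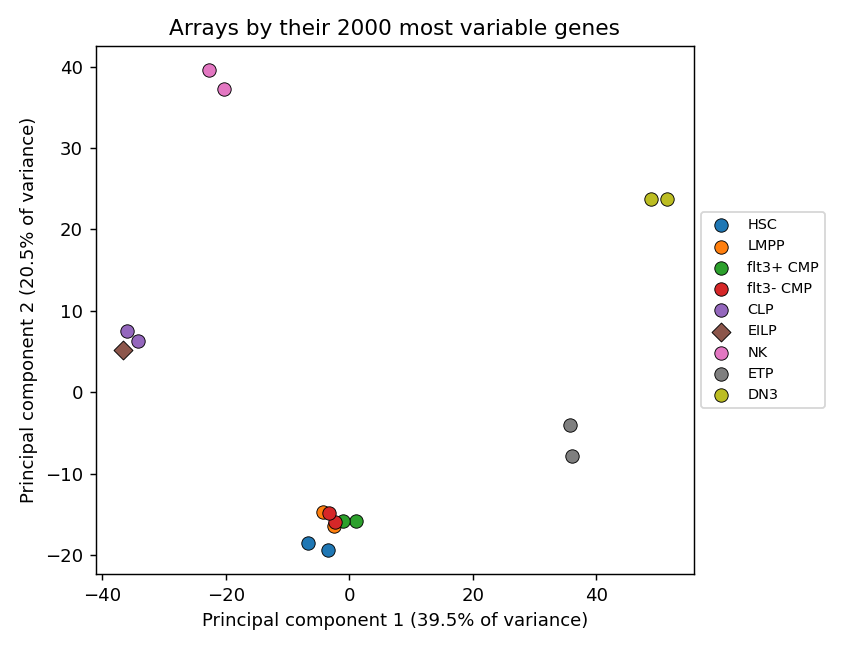
Each array placed by principal components 1 (39.5% of variance) and 2 (20.5%) of the 2000 most variable genes, coloured by population, with a diamond for EILP. EILP lay beside the 2 CLP arrays, apart from NK, from the HSC, LMPP and CMP arrays, and from the thymus arrays.

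The comparison of EILP with CLP sets the pool sorted as innate lymphoid progenitors against the pools sorted as common lymphoid progenitors. B lineage and lymphoid priming genes were lower in EILP than in CLP as groups. The B lineage list did not shift between EILP and LMPP (camera adjusted p = 0.85) or between EILP and ETP (camera adjusted p = 0.44). In CLP against LMPP, 13 of 15 B lineage genes were higher at an unadjusted p under 0.05. As a group, the B lineage difference thus lay with high values in CLP. Whether the make-up of the CLP pools accounts for it was not tested. Igll1, a surrogate light chain of the pre-B cell receptor, fell by 5.18 ± 0.34 (log2, SE, n = 1 against 2, adjusted p = 9e-06). It was high in CLP alone, at 9.32, against 4.14 in EILP and 4.15 to 4.67 in the other populations. Ebf1, a transcription factor required for B cell commitment, fell by 3.61 ± 0.39 (adjusted p = 0.00064), and Il7r, the interleukin 7 receptor, fell by 3.66 ± 0.34 (adjusted p = 0.00016). In EILP, Igll1 at 4.14 and Ebf1 at 3.69 lay below the median of all values, 4.54, so the size of their falls is uncertain. Higher in EILP were Cpa3, a mast cell protease also made by progenitors, by 2.90 ± 0.41 (adjusted p = 0.0057), and Tox, a transcription factor needed for innate lymphoid and T cell development, by 2.60 ± 0.31 (adjusted p = 0.0014). Ikzf2, an Ikaros family transcription factor, rose by 1.98 ± 0.26 (adjusted p = 0.0035). At 6.63 in EILP, it was still below every population except CLP, at 4.65.

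Of 22180 genes, 81 differed between EILP and CLP, 9 higher and 72 lower in EILP, 78 of them at least 2-fold. With each array centred, 5 were higher and 82 lower. An unadjusted count is larger, as 1917 genes had an unadjusted p under 0.05. Replicate against replicate of 1 population gave 0 (flt3- CMP) to 19 (NK) calls, with at most 15 in 1 direction. That is above the 9 higher genes and below the 72 lower ones. These pairs set 1 array against 1, not 1 against 2, and cannot show how far the lone EILP array varies. The other lower genes named by the rule were Emp1 at -4.18, Vpreb2 at -3.53, Blnk at -3.53, Slamf6 at -3.41, Ly6d at -3.39, the linker histone gene H1f1 at -3.19 and Akap12 at -3.15. Klrk1, which encodes the activating receptor NKG2D, was higher by 1.49 ± 0.27, Med12l by 1.41, Wnt9a by 1.15 and Olfr772 by 1.01. The calls of Klrk1 (1.44), Med12l (1.54), Wnt9a (0.99) and Emp1 (-3.84) were lost without CLP replicate 1. Those of Klrk1 (1.55), Med12l (1.28), Wnt9a (1.30) and Olfr772 (0.83) were lost without CLP replicate 2, when the count was 48. With only the 2 groups in the limma fit, no gene was called (0, with 2474 at an unadjusted p under 0.05). With only the CLP, EILP and DN3 arrays, chosen after seeing the data, 22 were. There 6 of the 7 genes named as higher lost their call with their differences unchanged, Cpa3 (2.90, adjusted p = 0.063), Ikzf2 (1.98, adjusted p = 0.081), Klrk1 (1.49, adjusted p = 0.12), Med12l (1.41, adjusted p = 0.2), Wnt9a (1.15, adjusted p = 0.24) and Olfr772 (1.01, adjusted p = 0.28), and Tox kept it.

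By list, 9 of 15 B lineage genes were lower in EILP than in CLP, 13 when adjusted over the list alone (camera adjusted p = 8.4e-35, and adjusted p = 0.00068 with an estimated correlation), with Cd79b at -2.79 and Vpreb3 at -2.53. Of 12 lymphoid priming genes 4 fell, 6 when adjusted over the list alone (adjusted p = 1.2e-13), among them Dntt at -3.08 and Rag2 at -3.07, which act in antigen receptor gene rearrangement. Innate lymphoid transcription factors shifted up as a group (adjusted p = 2.1e-05). Of 14, Tox and Ikzf2 rose and Lef1 fell by 3.05 ± 0.28, and 7 were higher and 2 lower when adjusted over the list alone. Zbtb16 at 1.31 ± 0.35, Nfil3 at 1.19 ± 0.33, Id2 at 0.86 ± 0.28 and Rora at 0.75 ± 0.18 did not pass the test over all genes. NK cell and cytotoxic genes shifted up (adjusted p = 3.6e-06, and adjusted p = 0.049 with an estimated correlation), with 1 of 24 called, Klrk1, and 6 when adjusted over the list alone. Cell division genes shifted down (adjusted p = 4.9e-09) and so did DNA replication genes (adjusted p = 5.8e-05), with 0 of 19 called in each list. With an estimated correlation the camera adjusted p of each was 0.031. Of cell division and DNA replication genes, 4 and 0 were lower when adjusted over the list alone, and 5 and 6 at an unadjusted p under 0.05. Mature B and plasma cell markers also shifted down (adjusted p = 0.0085, and adjusted p = 0.049 with an estimated correlation), with 1 of 12 lower and 3 when adjusted over the list alone. The 1 call did not hold without CLP replicate 1 or CLP replicate 2. Their median log2 change was 0.01 and their mean -0.39.

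Other shifts between EILP and CLP were lost with the estimated correlation. They were those of innate lymphoid receptors and surface proteins (adjusted p = 0.005, and adjusted p = 0.096 with an estimated correlation), granulocyte and monocyte genes (adjusted p = 0.048, and adjusted p = 0.42 with an estimated correlation). The same holds for macrophage markers (adjusted p = 0.0093, and adjusted p = 0.075 with an estimated correlation) and immediate early and stress genes (adjusted p = 0.031, and adjusted p = 0.32 with an estimated correlation). Red cell markers (adjusted p = 0.67), T lineage genes (adjusted p = 0.7), Notch target genes (adjusted p = 0.54), dendritic cell genes (adjusted p = 0.68), interferon response genes (adjusted p = 0.28) and lymphoid effector cytokines (adjusted p = 0.071) did not shift between EILP and CLP by this test. Nor did stem and multipotent progenitor genes (adjusted p = 0.094), megakaryocyte and erythroid genes (adjusted p = 1), mature T cell markers (adjusted p = 0.7), stromal and endothelial markers (adjusted p = 0.67), thymic epithelial markers (adjusted p = 0.31) and the sex-linked genes (adjusted p = 0.95). Of the 81 calls, 2 were among the genes that follow the neutrophil transcripts.

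**Figure D3:**
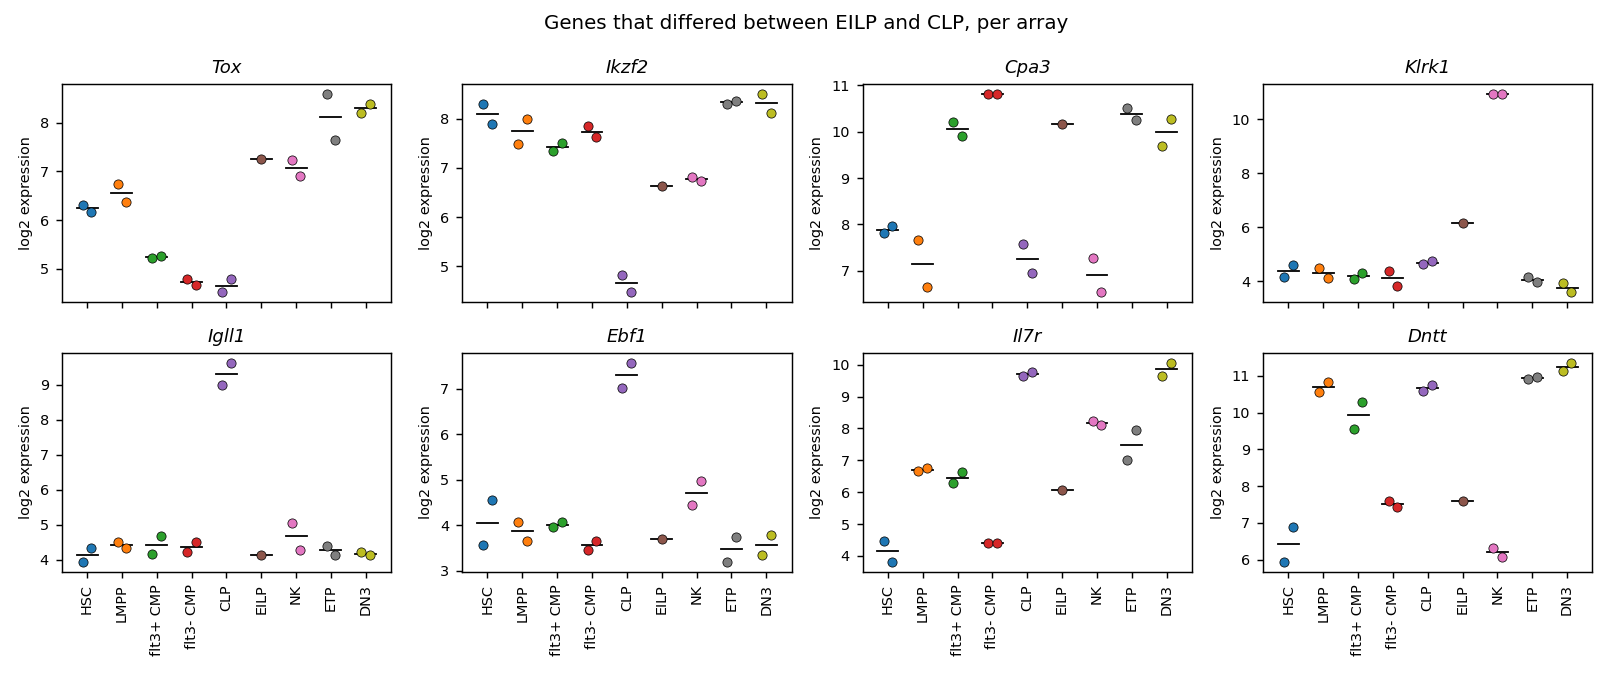
Log2 expression of Tox, Ikzf2, Cpa3, Klrk1, Igll1, Ebf1, Il7r and Dntt in each array by population, with points for arrays and a line for the mean of each population. EILP lay above CLP for the first 4 genes, with Tox at 7.25 against a CLP mean of 4.65, and below it for the other 4, with Igll1 at 4.14 against 9.32.

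Against LMPP, a less mature progenitor, EILP had lower stem cell and lymphoid priming gene expression and higher expression of NK cell, granulocyte, red cell and macrophage genes. The granulocyte and red cell rises were not particular to EILP. In CLP against LMPP, 15 of 21 granulocyte and monocyte genes and 7 of 7 red cell markers were higher at an unadjusted p under 0.05. Of 12 macrophage markers, 4 were higher and 2 lower there. Flt3, the receptor tyrosine kinase by which lymphoid-primed progenitors are sorted, fell by 3.65 ± 0.43 (n = 1 against 2, adjusted p = 0.00034), and Emp1, a membrane protein, fell by 5.67 ± 0.65 (adjusted p = 0.0003). Emp1 was at 3.54 in EILP, below the median of all values, 4.54, so the size of its fall is uncertain. Il1b, the inflammatory cytokine interleukin 1 beta, was higher by 4.09 ± 0.50 (adjusted p = 0.00045), and Clec7a, a receptor for fungal glucans on myeloid cells, by 3.55 ± 0.30 (adjusted p = 3.3e-05). Both were high in CLP too, with Il1b at 8.60 against 8.68 in EILP and Clec7a at 8.02 against 8.78. Id2, a transcription regulator that restrains B and T cell fates, rose by 2.28 ± 0.28 (adjusted p = 0.00046).

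Between EILP and LMPP 864 genes differed, 466 higher and 398 lower, 711 of them at least 2-fold, and without LMPP replicate 2 the count was 477. Of the 864 calls, 221 (25.6%) were among the genes that follow the neutrophil transcripts. Of 18 stem and multipotent progenitor genes 4 fell, and 4 when adjusted over the list alone (adjusted p = 1.1e-05), with Meis1 at -3.13, Angpt1 at -2.98 and Hlf at -2.51. Of 12 lymphoid priming genes 5 fell, 6 when adjusted over the list alone (adjusted p = 6.8e-08). Of 24 NK cell and cytotoxic genes 8 rose, 9 when adjusted over the list alone (adjusted p = 2.6e-09), with Cd7 at 2.03 and Klrk1 at 1.88. Among innate lymphoid transcription factors, the list shifted up (adjusted p = 0.0018), with 1 higher and 1 lower of 14, and 4 and 1 when adjusted over the list alone. Markers of other cells rose too, with 8 of 21 granulocyte and monocyte genes (15 when adjusted over the list alone, adjusted p = 7.6e-15). So did 5 of 7 red cell markers (7, adjusted p = 2.6e-10), with Rhag at 2.61, and 4 of 12 macrophage markers (5, adjusted p = 7.9e-05), with Slc40a1 at 2.12. Dendritic cell genes rose in 3 of 13 (4 when adjusted over the list alone, adjusted p = 0.00021). Megakaryocyte and erythroid genes rose in 3 of 15 (4 over the list alone, adjusted p = 3.1e-05, and adjusted p = 0.021 with an estimated correlation). Without LMPP replicate 2, fewer genes were called higher in the NK cell and cytotoxic, granulocyte and monocyte, and red cell lists. The 1 lower innate lymphoid transcription factor, Ikzf2, was at -0.87 there. Fewer macrophage markers were called without LMPP replicate 1. The receptor list shifted up (adjusted p = 0.013, and adjusted p = 0.13 with an estimated correlation).

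Other genes named by the rule as higher in EILP than in LMPP were the Y-linked Eif2s3y (5.22), Kdm5d (3.34) and Uty (3.02), Apol11b (4.76), Sirpb1c (4.25), Jchain (3.41), which joins antibody units, Clec4a1 (3.31) and Cpa3 (3.01). Apol11b, Sirpb1c, Jchain and Clec4a1 were high in CLP as well, at 6.84 to 8.04. The lower ones were Gprasp2 (-4.45), the histone gene H2bc12 (-4.03), Emcn (-3.77), Tspan6 (-3.64), Myct1 (-3.60), Bex1 (-3.51), Adgrl4 (-3.49) and Ctla2b (-3.41). The sex-linked list differed in all 4 members measured, 3 higher and 1 lower, since EILP and LMPP lie on different sides of that split.

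Against NK cells, which are mature innate lymphocytes, EILP had lower expression of most cytotoxic genes. Of 24 NK cell and cytotoxic genes 19 were lower in EILP, 21 when adjusted over the list alone (adjusted p = 9.8e-48, and adjusted p = 0.00038 with an estimated correlation). Ncr1, the activating receptor NKp46, fell by 5.48 ± 0.24 (n = 1 against 2, adjusted p = 1.8e-08), and Gzmb, a protease of cytotoxic granules, fell by 5.33 ± 0.38 (adjusted p = 1.6e-06). Eomes, a T-box transcription factor of NK cells, fell by 5.07 ± 0.27 (adjusted p = 8.9e-08). Higher in EILP was Cpa3, by 3.25 ± 0.41 (adjusted p = 0.00033), and Apol11b, by 4.16 ± 0.25 (adjusted p = 3.5e-07).

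Between EILP and NK 772 genes differed, 349 higher and 423 lower, 645 of them at least 2-fold. With only the 2 groups in the fit 125 did. Among the genes named as lower were members of the killer cell lectin-like receptor family, Klri2 (-6.31), Klra9 (-6.30), Klre1 (-6.15), Klrc2 (-5.54), Klrc1 (-5.36) and Klrd1 (-5.33). In EILP, Klri2 at 3.32, Klra9 at 3.45, Klrc2 at 2.77 and Klrc1 at 4.29 lay below the median of all values, 4.54, so the size of their falls is uncertain. Members of this family are near-identical in part, so probe sets can cross-hybridise and single members are uncertain. Samd3 (-5.57) and Cd226 (-5.48), an adhesion receptor of NK cells, were also lower, and these genes and Gzmb lay below that median in EILP too (3.44, 3.82 and 3.57). Of 14 innate lymphoid transcription factors 5 fell, 6 when adjusted over the list alone (adjusted p = 1.8e-05), among them Tbx21 at -2.23 and Id2 at -1.56. Of 14 T lineage genes 6 were lower, 8 when adjusted over the list alone (adjusted p = 4.4e-06), with Thy1 at -4.00 and Cd3g at -3.50. Over the list alone, 2 were higher. Granulocyte and monocyte genes shifted up (adjusted p = 4e-10), with 4 of 21 higher, 11 when adjusted over the list alone. Of all calls, 114 of the 772 calls (14.8%) follow the neutrophil transcripts. Macrophage markers shifted up as well (2 of 12, 1 without NK replicate 2, and 4 when adjusted over the list alone, adjusted p = 0.00033).

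Some shifts between EILP and NK were lost with the estimated correlation. They were mature T cell markers (3 of 11 lower, adjusted p = 0.0011, and adjusted p = 0.074 with an estimated correlation), immediate early and stress genes (adjusted p = 0.0047, and adjusted p = 0.15 with an estimated correlation). Lost too were DNA replication genes (adjusted p = 0.0047, and adjusted p = 0.074 with an estimated correlation), cell division genes (adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation) and red cell markers (adjusted p = 0.011, and adjusted p = 0.064 with an estimated correlation). Also lost were megakaryocyte and erythroid genes (adjusted p = 0.011, and adjusted p = 0.13 with an estimated correlation) and B lineage genes (adjusted p = 0.047, and adjusted p = 0.27 with an estimated correlation). Further genes named as higher in EILP than in NK were Clec4a1 (3.31), Bex6 (2.84), Sirpb1c (2.78), Egln3 (2.78), an oxygen sensor of the hypoxia response, and Tlr13 (2.68), whose call was lost without NK replicate 1 (1.79). The Y-linked genes Eif2s3y (5.35), Kdm5d (3.49) and Uty (2.96) were named too, as this comparison crosses the split in Y-linked transcripts.

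Against ETP, the thymic progenitor, EILP had higher expression of granulocyte and cell division genes and lower expression of lymphoid priming and Notch target genes. Hes1, a direct Notch target, fell by 2.76 ± 0.18 (n = 1 against 2, adjusted p = 3.3e-07), and Rag2, part of the antigen receptor recombinase, fell by 3.03 ± 0.32 (adjusted p = 2.8e-05). Mki67, a marker of dividing cells, rose by 1.68 ± 0.18 (adjusted p = 3.6e-05), and Id2 rose by 1.97 ± 0.28 (adjusted p = 0.00045). Mki67 was at 8.82 to 8.95 in ETP and at 9.90 or more in every other array, HSC and NK included. Its difference thus sets ETP apart from all other populations rather than EILP. The genes with the largest increase were neutrophil genes, such as Camp by 7.73 ± 0.30 (adjusted p = 3.4e-09). In ETP, Camp at 4.33, Chil3 at 4.15, Stfa2l1 at 3.37 and Retnlg at 3.18 lay below the median of all values, 4.54. The size and rank of their rises are uncertain.

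Between EILP and ETP 1817 genes differed, 1062 higher and 755 lower, 1429 of them at least 2-fold. With only the 2 groups fitted 855 did. Of 21 granulocyte and monocyte genes 17 rose, 20 when adjusted over the list alone (adjusted p = 1.1e-37). All 10 genes named as higher (Camp, Chil3 at 7.82, Stfa2l1, Ltf, Retnlg, Ifitm6, Mmp8, Cybb, Ly6c2, and Ngp at 6.88) are expressed by neutrophils or monocytes. Stfa2l1 belongs to a family of near-identical copies, so its probe set can cross-hybridise and its value is uncertain. The comparison is also one of marrow with thymus and crosses the split in Y-linked transcripts (Xist at -2.51), and S100a8 was at 11.95 or more in every marrow array. Red cell markers rose in 7 of 7 (7 when adjusted over the list alone, adjusted p = 1.2e-10) and macrophage markers in 4 of 12 (5, adjusted p = 3.1e-05). So did megakaryocyte and erythroid genes in 4 of 15 (6, adjusted p = 8.1e-06) and dendritic cell genes in 4 of 13 (5, adjusted p = 0.0021). Immediate early and stress genes (adjusted p = 0.03, and adjusted p = 0.29 with an estimated correlation) and mature B and plasma cell markers (adjusted p = 0.02, and adjusted p = 0.052 with an estimated correlation) shifted up. Of 19 cell division genes 18 rose, 18 when adjusted over the list alone (adjusted p = 6e-25). Of 19 DNA replication genes 5 rose, 5 over the list alone (adjusted p = 0.00017). Of the 1817 calls, 307 (16.9%) follow the neutrophil transcripts.

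Of 12 lymphoid priming genes, 8 were lower in EILP than in ETP, 8 when adjusted over the list alone (adjusted p = 2e-08), with Dntt at -3.36 and Notch1 at -1.93. Of 10 Notch target genes 4 were lower, 4 over the list alone (adjusted p = 2.4e-05), among them Il2ra at -1.99 and Myc at -1.05. Of 14 T lineage genes 2 were, 5 over the list alone (adjusted p = 0.0033). Innate lymphoid transcription factors did not shift as a group (adjusted p = 0.29). Of 14, 3 were higher, such as Nfil3 at 1.88, and Ikzf2 was lower at -1.70 (2 lower without ETP replicate 1 or ETP replicate 2), with 4 and 2 over the list alone. NK cell and cytotoxic genes went both ways, 6 higher and 3 lower of 24, and 8 and 6 when adjusted over the list alone (adjusted p = 0.029, and adjusted p = 0.29 with an estimated correlation). The other genes named as lower were Emp1 (-6.08), Olfr649 (-5.75), Tmem108 (-4.32), Rgs1 (-4.24), Lax1 (-4.16), Fasl (-4.02), the death receptor ligand, Angpt1 (-3.98), Ctla2b (-3.66), Tsc22d1 (-3.64) and Il1r1 (-3.41).

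Genes that set EILP apart from each of the 8 other populations were few. Higher were Olfr772, an olfactory receptor gene, by at least 1.01 (largest adjusted p = 0.039, but at 4.19 in EILP and so below the median of all values, 4.54, in every population), and the antibody gene segment Ighv1-53, named here because the count is small, by at least 2.04 (largest adjusted p = 0.033). Lower were Fam136a (-1.60 against the nearest population), Mgat4a (-1.30), the B cell receptor gene Cd79b (-1.14), Esf1 (-1.06) and Ddx10 (-1.04), of which the last 2 act in ribosome production. The counts of 2 and 5 rest on single arrays. The higher count was 1 without dim genes, which leaves out Olfr772. It was 0 without any 1 of the arrays of LMPP, flt3+ CMP and flt3- CMP or HSC replicate 2 (11 to 13 genes at an unadjusted p under 0.05) and 4 without CLP replicate 1. The lower count was 1 without CLP replicate 2.

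LMPP differed from HSC by the start of lymphoid gene expression and lower stem cell and megakaryocyte gene expression. Dntt, the polymerase that adds bases to rearranging antigen receptor genes, rose by 4.28 ± 0.28 (n = 2 and 2, adjusted p = 9.6e-06), Il7r by 2.57 ± 0.28 (adjusted p = 0.00056) and Satb1, a chromatin organiser of lymphoid cells, by 2.20 ± 0.16 (adjusted p = 1.5e-05). Slamf1, the stem cell surface protein CD150, fell by 2.28 ± 0.18 (adjusted p = 3e-05), and Mecom, a transcription factor of stem cell renewal, fell by 1.61 ± 0.19 (adjusted p = 0.0011). Of 12 lymphoid priming genes 5 rose, 8 when adjusted over the list alone (adjusted p = 7.4e-17). Of 18 stem and multipotent progenitor genes 6 fell, 14 over the list alone (adjusted p = 8.4e-27). Of 15 megakaryocyte and erythroid genes 3 fell, 8 over the list alone (adjusted p = 6.9e-13). Without LMPP replicate 1, LMPP replicate 2 or HSC replicate 1, the counts of the last 2 lists fell to 3 and 0. Cell division genes shifted up with 0 of 19 called (0 over the list alone, 7 higher at an unadjusted p under 0.05, adjusted p = 1.3e-05, and adjusted p = 0.11 with an estimated correlation). Red cell markers shifted down (adjusted p = 0.017, and adjusted p = 0.099 with an estimated correlation).

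Between LMPP and HSC 133 genes differed, 61 higher and 72 lower, 112 of them at least 2-fold. The other named genes that rose were Emp1 (4.77), Tmem108 (3.01), Il1r1 (2.94), Tlr7 (2.88), a sensor of RNA, Sema3d (2.62) and Flt3 (2.54). Those that fell were Plxdc2 (-3.17), Slc18a2 (-3.01), a transporter of monoamines, Trpc6 (-2.83), Olfr417 (-2.77), Pf4 (-2.51), a platelet chemokine, Pcdh7 (-2.40) and Dach1 (-2.23). The call of Tmem108 was lost without LMPP replicate 1 (2.51), HSC replicate 1 (2.75) or HSC replicate 2 (3.27). That of Pf4 was lost without LMPP replicate 1 (-2.70), LMPP replicate 2 (-2.33) or HSC replicate 1 (-1.91), and that of Flt3 without LMPP replicate 2 (2.22). The count was 69 without LMPP replicate 1, 66 without LMPP replicate 2, 57 without HSC replicate 1, and 29 with only the 2 groups fitted.

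The flt3+ and flt3- CMP differed in few genes, with lymphoid priming genes higher in flt3+ cells. Dntt rose by 2.42 ± 0.28 (n = 2 and 2, adjusted p = 0.008), Il7r by 2.05 ± 0.28 (adjusted p = 0.023) and Rag2 by 1.63 ± 0.26 (adjusted p = 0.037), and Emp1 by 3.56 ± 0.53 (adjusted p = 0.035). Prg2, the major basic protein of eosinophil granules, fell by 2.70 ± 0.34 (adjusted p = 0.015), and Blvrb, an enzyme of heme breakdown, fell by 1.55 ± 0.23 (adjusted p = 0.035). Of 12 lymphoid priming genes 3 rose, 5 when adjusted over the list alone (adjusted p = 6.3e-07), and 0 or 1 were called without any 1 of the 4 arrays. Megakaryocyte and erythroid genes shifted down (adjusted p = 2.8e-11), with 0 of 15 called, 8 lower over the list alone and 9 lower at an unadjusted p under 0.05. Red cell markers shifted down as well (0 of 7 called, 3 lower over the list alone and 3 at an unadjusted p under 0.05, adjusted p = 0.00034), and so did DNA replication genes (0 of 19, 0 over the list alone and 7 lower at an unadjusted p under 0.05, adjusted p = 0.00034). Cell division genes (adjusted p = 0.00058, and adjusted p = 0.21 with an estimated correlation) and innate lymphoid receptors (adjusted p = 0.0012, and adjusted p = 0.1 with an estimated correlation) shifted up.

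In all, 24 genes differed between flt3+ and flt3- CMP, 10 higher and 14 lower, 20 of them at least 2-fold, with 2065 at an unadjusted p under 0.05. The other named genes were Mss51 (1.29) and Sparc (1.16), which rose, and Aqp1 (-1.67), a water channel of red cells, Pcdh7 (-1.58), C1qtnf12 (-1.45), Mfsd2b (-1.32), Slc35c2 (-1.28) and Pfkl (-1.25), which fell. The split of calls depends on the scaling, as 41.7% were higher as deposited, 66.7% of 9 with each array centred and 90.9% of 11 after quantile normalization. Every left-out array lowered the count, to 6 without flt3+ CMP replicate 1 (Dntt and Sparc kept their call), 4 without flt3+ CMP replicate 2, 2 without flt3- CMP replicate 1 and 1 without flt3- CMP replicate 2. In the last 3 fits all 14 named genes lost their call, with Dntt at 2.05, 2.50 and 2.34 and Prg2 at -2.62, -2.80 and -2.60.

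CLP differed from LMPP by the B lineage program and by lower stem cell gene expression. Igll1 rose by 4.88 ± 0.28 (n = 2 and 2, adjusted p = 3.6e-07), Ebf1 by 3.43 ± 0.32 (adjusted p = 2.5e-05) and Il7r by 3.01 ± 0.28 (adjusted p = 2.4e-05). In all, 13 of 15 B lineage genes rose, 13 when adjusted over the list alone (adjusted p = 1.7e-26). Meis1, a homeobox gene of stem cells, fell by 3.26 ± 0.19 (adjusted p = 4.5e-07), with 4 of 18 stem and multipotent progenitor genes lower, 5 over the list alone (adjusted p = 2e-08). Tox fell by 1.91 ± 0.25 (adjusted p = 0.00046) and Ikzf2 fell by 3.09 ± 0.21 (adjusted p = 1.7e-06), while Lef1 rose by 3.26 ± 0.23 (adjusted p = 2.1e-06). The innate lymphoid transcription factors did not shift as a group (adjusted p = 0.89). Cell division genes rose in 8 of 19 (15 over the list alone, adjusted p = 2.1e-12) and DNA replication genes in 2 of 19 (5, adjusted p = 3.4e-05). Granulocyte and monocyte genes rose in 9 of 21 (15 over the list alone, adjusted p = 3.9e-13), red cell markers in 6 of 7 (7, adjusted p = 7.3e-13). Dendritic cell genes rose in 5 of 13 (6, adjusted p = 3.9e-06) and megakaryocyte and erythroid genes in 4 of 15 (7, adjusted p = 3.9e-06). Several of these counts rest on single arrays. Leaving out 1 array gave 1 to 4 for cell division genes, 0 to 2 for DNA replication genes, 4 to 7 for granulocyte and monocyte genes and 3 to 4 for dendritic cell genes.

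Between CLP and LMPP 1321 genes differed, 832 higher and 489 lower, 825 of them at least 2-fold, and 271 (20.5%) follow the neutrophil transcripts. Centring each array moved the median of all genes by 0.104 and the share of higher calls from 63.0% to 75.5%. Leaving out 1 array gave 749 (CLP replicate 1), 636 (CLP replicate 2), 708 (LMPP replicate 1) or 717 (LMPP replicate 2) calls. The comparison crosses the split in Y-linked transcripts, and the Y-linked Eif2s3y (5.31) and Kdm5d (3.91) were among the named genes. The other named genes that rose were Jchain (4.06), Il1b (4.01), the heat shock gene Hspa1b (3.92), Apol11b (3.88) and Ly6d (3.86), a surface marker of B-primed progenitors. Those that fell were Ctla2b (-4.39), Emcn (-4.11), Bex1 (-3.81), Il1r1 (-3.70), Adgrl4 (-3.64), Angpt1 (-3.59) and Gprasp2 (-3.50). Immediate early and stress genes (adjusted p = 0.00076, and adjusted p = 0.099 with an estimated correlation) and NK cell and cytotoxic genes (adjusted p = 0.005, and adjusted p = 0.17 with an estimated correlation) shifted up. So did macrophage markers (adjusted p = 0.026, and adjusted p = 0.099 with an estimated correlation) and mature B and plasma cell markers (adjusted p = 0.024, and adjusted p = 0.069 with an estimated correlation).

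NK cells differed from CLP by the cytotoxic program and its transcription factors, with lower B lineage and lymphoid priming genes. Of 24 NK cell and cytotoxic genes 21 rose, 21 when adjusted over the list alone (adjusted p = 2.8e-47), such as Ncr1 by 6.19 ± 0.20 (n = 2 and 2, adjusted p = 3.8e-10) and Il2rb, a receptor chain for interleukins 2 and 15, by 6.17 ± 0.22 (adjusted p = 7e-10). Of 14 innate lymphoid transcription factors 9 rose, 13 over the list alone (adjusted p = 5.9e-13), among them Eomes by 5.42 ± 0.22, Tbx21 by 2.66 ± 0.16, Tox by 2.42 ± 0.25 and Ikzf2 by 2.13 ± 0.21. Of 15 B lineage genes 12 fell and 1 rose, 13 and 2 over the list alone (adjusted p = 1.2e-18). Of 12 lymphoid priming genes 6 fell and 1 rose, 8 and 2 over the list alone (adjusted p = 1.3e-07). Of 14 T lineage genes 7 rose, 7 over the list alone (adjusted p = 1.5e-06), with Cd3g at 4.41. Cell division genes fell in 8 of 19 (15 over the list alone, adjusted p = 1e-13) and DNA replication genes in 3 of 19 (12, adjusted p = 6.5e-11). Granulocyte and monocyte genes fell in 6 and rose in 1 of 21 (9 and 1, adjusted p = 3.4e-08). Leaving out 1 array gave 1 to 7 lower cell division genes (1 without CLP replicate 1 or CLP replicate 2), 1 to 5 lower DNA replication genes, 3 to 6 lower granulocyte and monocyte genes and 4 to 5 higher T lineage genes. The single higher genes of 3 lists lost their call too. Those were Ccr2 of the granulocyte and monocyte list without any 1 of the 4 arrays (0.83 to 1.26), Ms4a1 of the B lineage list without any 1 but NK replicate 2 (0.52 to 0.87), and Ltb of the lymphoid priming list without NK replicate 1 (1.03) or CLP replicate 1 (0.96).

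Lymphoid effector cytokines rose in 3 and fell in 1 of 12 between CLP and NK, 3 and 1 when adjusted over the list alone (adjusted p = 0.0044), with Ifng, the cytokine interferon gamma, at 4.18. The 1 that fell, Tnf, lost its call without NK replicate 1 (-0.67), CLP replicate 1 (-1.29) or CLP replicate 2 (-0.96). Mature T cell markers rose in 3 of 11 (5 over the list alone, adjusted p = 0.0002). Stromal and endothelial markers shifted up (2 of 12 higher, 3 over the list alone, adjusted p = 0.034, and adjusted p = 0.075 with an estimated correlation), and so did innate lymphoid receptors and surface proteins (adjusted p = 0.018, and adjusted p = 0.12 with an estimated correlation). Red cell markers shifted down (adjusted p = 0.00069), with 1 of 7 lower (0 in 3 of the 4 fits without 1 array) and 3 over the list alone. Megakaryocyte and erythroid genes shifted down too (2 of 15 lower, 0 to 1 without 1 array, 4 over the list alone, adjusted p = 0.0062, and adjusted p = 0.078 with an estimated correlation). Between NK and CLP 1418 genes differed, 715 higher and 703 lower, 791 of them at least 2-fold, and 145 (10.2%) follow the neutrophil transcripts. Centring each array moved the median of all genes by -0.146 and the share of higher calls from 50.4% to 28.3%. The count was 748 without CLP replicate 1, 740 without CLP replicate 2 and 564 with only the 2 groups fitted. Named as higher were also the lectin-like receptor genes Klra9 (7.04), Klri2 (6.64), Klre1 (6.63), Klrk1 (6.27), Klrc1 (5.94) and Klrc2 (5.89), whose probe sets can cross-hybridise. All but Klrk1 lay below the median of all values, 4.54, in CLP, at 2.42 (Klrc2) to 4.35 (Klre1). The size of their rises is therefore uncertain. Named as lower were the Y-linked Eif2s3y (-5.44) and Kdm5d (-4.06), as the comparison crosses the split in Y-linked transcripts. The other lower ones were Igll1 (-4.64), Dntt (-4.47), Emp1 (-3.60), Fabp4 (-3.59), Blnk (-3.43) and Rag2 (-3.41).

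ETP differed from LMPP by the first T lineage and Notch target genes, and by lower granulocyte and cell division genes. Hes1 rose by 3.21 ± 0.14 (n = 2 and 2, adjusted p = 1.2e-08), Cd7, a surface protein of early T and NK cells, by 3.87 ± 0.28 (adjusted p = 2.1e-06). Il2ra, the interleukin 2 receptor alpha chain, rose by 2.22 ± 0.18 (adjusted p = 5.6e-06). Of 14 T lineage genes 6 rose, 6 when adjusted over the list alone (adjusted p = 1.7e-07) and 2 without LMPP replicate 1, with Cd3g at 1.99 and Trat1 at 1.75. Of 10 Notch target genes 3 rose, 4 over the list alone (adjusted p = 5.8e-06). Of 18 innate lymphoid receptors and surface proteins 4 rose, 4 over the list alone (adjusted p = 1.9e-05). Of 19 cell division genes 17 fell, 19 over the list alone (adjusted p = 5.5e-35), with Cdk1, the kinase that drives mitosis, at -1.74 and Top2a at -1.39. DNA replication genes went the same way, with 7 of 19 lower and 0 higher at an unadjusted p under 0.05. Of 21 granulocyte and monocyte genes 16 fell, 16 over the list alone (adjusted p = 7.1e-34), in a comparison of thymus with marrow arrays in which S100a8 fell by 6.42 ± 0.57 (adjusted p = 1.3e-05).

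Between ETP and LMPP 759 genes differed, 226 higher and 533 lower, 540 of them at least 2-fold, and 126 (16.6%) follow the neutrophil transcripts. The count was 447 without LMPP replicate 1, 472 without LMPP replicate 2 and 315 with only the 2 groups fitted. The other named genes that rose were Olfr649 (5.50), Fasl (4.03), Deptor (3.51), an inhibitor of mTOR, Tsc22d1 (3.48), Scin (3.35) and Cpa3 (3.23). Those that fell were neutrophil or monocyte genes, Camp (-6.85), Retnlg (-6.63), Chil3 (-6.36), Ngp (-6.13), Ifitm6 (-5.96), Stfa2l1 (-5.88) and Ly6c2 (-5.57). Some shifts were lost with the estimated correlation. They were stem and multipotent progenitor genes (down, adjusted p = 1.9e-05, and adjusted p = 0.052 with an estimated correlation), NK cell and cytotoxic genes (up, adjusted p = 0.0055, and adjusted p = 0.17 with an estimated correlation) and red cell markers (down, adjusted p = 0.013, and adjusted p = 0.059 with an estimated correlation). Also lost were megakaryocyte and erythroid genes (down, adjusted p = 0.044, and adjusted p = 0.18 with an estimated correlation) and mature B and plasma cell markers (down, adjusted p = 0.044, and adjusted p = 0.1 with an estimated correlation).

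DN3 differed from ETP by the full T lineage program and by cell division genes. Cd3g, Cd3e and Cd3d, parts of the T cell receptor complex, rose by 6.42 ± 0.27, 6.25 ± 0.25 and 5.75 ± 0.36 (n = 2 and 2, adjusted p = 5e-09, 3.2e-09 and 3e-07). Bcl11b, a transcription factor of T cell commitment, rose by 4.12 ± 0.16 (adjusted p = 2.6e-09). Of 14 T lineage genes 13 rose, 14 when adjusted over the list alone (adjusted p = 2.1e-30). Of 10 Notch target genes 5 rose, 7 over the list alone (adjusted p = 3e-07), with Il2ra at 4.25 and Notch3 at 1.05. Of 19 cell division genes 19 rose, 19 over the list alone (adjusted p = 3.1e-29), with Mki67 at 1.55. Of 19 DNA replication genes 15 rose, 17 over the list alone (adjusted p = 4.6e-15), and 7 were called without DN3 replicate 1 or DN3 replicate 2. Tyrobp, a signalling adaptor of NK and myeloid cells, fell by 5.87 ± 0.19 (adjusted p = 8.6e-10), and Cd34, a progenitor surface protein, fell by 5.09 ± 0.31 (adjusted p = 2.5e-07). Mpo, the granule enzyme myeloperoxidase, fell by 4.84 ± 0.23 (adjusted p = 2e-08).

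Between DN3 and ETP 1936 genes differed, 1154 higher and 782 lower, 1066 of them at least 2-fold, and 69 (3.6%) follow the neutrophil transcripts. The count was 1201 without DN3 replicate 1, 1115 without DN3 replicate 2 and 1083 with only the 2 groups fitted. The other named genes that rose were Themis (5.17), a regulator of T cell receptor signalling, Gbp4 (5.49), Gbp8 (5.41), the histone gene H2ac15 (4.71) and the Y-linked Eif2s3y (4.62), as the comparison crosses the split in Y-linked transcripts. The guanylate-binding protein and histone genes have near-identical copies whose probe sets can cross-hybridise. Those that fell were Olfr649 (-5.61), Car2 (-5.23), Il1r1 (4.46 in DN3 against 9.46 in ETP), Adgrl4 (-4.88) and Samhd1 (-4.79). Granulocyte and monocyte genes fell in 8 of 21, 10 over the list alone with 2 higher (adjusted p = 6.2e-05, and adjusted p = 0.15 with an estimated correlation). NK cell and cytotoxic genes fell in 8 and rose in 1 of 24, 8 and 1 over the list alone (adjusted p = 3.7e-06, and adjusted p = 0.071 with an estimated correlation). Megakaryocyte and erythroid genes (5 of 15 lower, 5 over the list alone, adjusted p = 0.012, and adjusted p = 0.15 with an estimated correlation) and dendritic cell genes (2 of 13, 2 over the list alone, adjusted p = 0.016, and adjusted p = 0.073 with an estimated correlation) shifted down. So did immediate early and stress genes (adjusted p = 0.048, and adjusted p = 0.32 with an estimated correlation). Interferon response genes did not shift (adjusted p = 0.1), with 4 of 13 lower (1 without any 1 of the 4 arrays) and 5 over the list alone. Thymic epithelial markers did not either (adjusted p = 0.36), with Epcam, an adhesion protein, higher at 2.53.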

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

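All alternatives were chosen before the data were examined except those that left out genes that follow the neutrophil transcripts (for the similarity, the sex-linked genes too), the NK and ETP arrays, or the arrays with or without Y-linked transcripts. Of 738 results for single genes, none reversed under any alternative run, and of 9153 values under the alternatives 8117 stayed on their side of the threshold and 1036 lost their call. Most of these genes were named because they were called. Leaving out dim genes or arrays not compared, or testing all probe sets, leaves the fold change as it was. The same holds for the variance prior and the replicate covariate. No reversal could occur there, so its absence does not measure stability. The comparison of flt3+ with flt3- CMP was among the least stable. With only the 2 groups compared it lost 10 of 14 gene results, while EILP against CLP lost 27 of 33. The 24 genes of flt3+ against flt3- CMP became 9 with each array centred, 11 after quantile normalization and 1 with all probe sets of the table (more features tested). They became 43 in the fit without the NK and ETP arrays and 1 with only the arrays without Y-linked transcripts. For EILP against CLP, the 9 higher genes became 5 with each array centred, and only the arrays with Y-linked transcripts gave 22 genes in place of 81. With only the 2 groups compared, and so 1 or 2 residual degrees of freedom, the limma counts were 0 for EILP against CLP (2474 at an unadjusted p under 0.05), 125 for EILP against NK, 855 for EILP against ETP, 29 for LMPP against HSC, 7 for flt3+ against flt3- CMP, 564 for NK against CLP, 315 for ETP against LMPP and 1083 for DN3 against ETP. A 2-fold threshold left 825 for CLP against LMPP, 791 for NK against CLP and 1066 for DN3 against ETP. Genes apart in EILP, higher, were 1 with each array centred, 1 after quantile normalization, 1 without dim genes and 15 with all probe sets, and the lower ones were 2 after quantile normalization. Of the 109 gene list shifts, 72 held with an estimated correlation. Leaving out the genes that follow the neutrophil transcripts took them from the same calls without a new fit. They were at most 25.6% of the calls of any comparison, so no count could move by more than 1.5 times. EILP stayed closest to CLP under each similarity setting. Where fewer arrays or more features do not account for a change, the cause was not tested.

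The replicate numbers showed no sign of pairing the samples, as the correlation of replicate differences between populations ran from -0.07 to 0.09 over 28 pairs. So low a correlation cannot exclude shared donors or sort days. With a replicate block, flt3+ against flt3- CMP gave 6 genes in place of 24, EILP against CLP 73 in place of 81, and 108 list shifts were called, and no other count moved by more than 1.5 times.

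Leaving out 1 array at a time, where the lone array left is assumed to vary like the other groups, gave 48 to 57 genes for EILP against CLP, 477 to 595 for EILP against LMPP, 602 to 736 for EILP against NK, 1474 to 1955 for EILP against ETP and 57 to 122 for LMPP against HSC. It gave 1 to 6 for flt3+ against flt3- CMP, 636 to 749 for CLP against LMPP, 740 to 1164 for NK against CLP, 447 to 979 for ETP against LMPP and 1115 to 1915 for DN3 against ETP. Genes apart in EILP numbered 0 to 4 higher (11 to 17 at an unadjusted p under 0.05) and 1 to 5 lower. Array values carry no depth, and the number of arrays limits what can be called.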

Other observations

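The tests of 2 explanations, a wider batch difference and RNA of neutrophils, were set before their results were seen, and all other tests and selections here were chosen after.

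EILP was also compared with the populations that the comparisons above leave out. It differed from HSC in 1121 genes (536 higher, 585 lower), from flt3+ CMP in 991 (540 higher, 451 lower), from flt3- CMP in 1584 (637 higher, 947 lower) and from DN3 in 2262 (1125 higher, 1137 lower). The olfactory receptor gene Olfr649 was at 8.10 in ETP and at 2.35 to 2.66 in the 8 other populations. Over 25 genes with histone cluster symbols, gathered after seeing the data, the median log2 difference was -0.80 for EILP minus CLP (20 below 0, 2 called lower, unadjusted camera p = 3.2e-11, and 0.0028 with an estimated correlation). It was -0.77 for ETP minus LMPP, 0.68 for DN3 minus ETP, 0.38 for EILP minus ETP and -0.24 to -0.64 for EILP minus each other population, and between replicates at most 0.30 in size. It was 0.14 for LMPP minus HSC, -0.07 for flt3+ minus flt3- CMP, 0.18 for CLP minus LMPP and -0.22 for NK minus CLP. Histone genes have near-identical copies, so probe sets can cross-hybridise and single members are uncertain.

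The arrays of CLP, EILP and DN3 have Y-linked transcripts and the other 12 do not. Pools that differ in the sex of the cells are a candidate explanation, and the lowest Xist of the 12 arrays lay 1.80 log2 units above the highest of the 5. Xist at 8.97 to 9.44 in CLP and EILP was above the 7.13 to 7.50 of DN3. A wider batch difference that runs with the split was tested by counting genes outside the sex-linked list that part the 5 arrays from the other 12 without overlap and by at least 1 log2 unit. There were 2, Kcnma1 (higher) and Ctla2b (lower), and 5 of the 84 choices of 3 populations, this one included, gave as many or more, the highest other being 9 for CLP, EILP and NK. By the limit set beforehand, 5% of the choices, this speaks against a wider batch difference, but the count of 5 is over that limit by less than 1 choice. Reading so small a margin as undecided was chosen after the count was seen. On that reading a batch difference was neither shown nor excluded, and it cannot be told apart from the populations.

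Transcripts of neutrophils were high in all 13 marrow arrays and low in the thymus arrays. RNA of neutrophils in the marrow pools is a candidate explanation, since 14 measured genes of a further neutrophil list were higher in the NK arrays than in the thymus arrays by a median of 2.51 log2 units, 12 of them by at least 1. Lcn2, an abundant one, was at 10.37 in NK against 4.86 in ETP and 5.08 in DN3, and none of these genes stands in the other lists, although Anxa1 and Hdc are also expressed by other cells. RNA of whole marrow with all its cell types was examined with the B lineage list. Its median in the HSC, LMPP, CMP and NK arrays lay only 0.15 above thymus, while that of the granulocyte list lay 2.73 above. A small share of such RNA could raise abundant neutrophil transcripts and leave the B lineage median in place, so this cannot decide. In EILP against ETP, 7 of 7 red cell markers were called higher, while of 15 B lineage genes 0 were higher and 1 lower. Whole marrow RNA therefore stays open. Expression by the sorted cells themselves stays open as untested, and the labels used here give no gate that would remove neutrophils.

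Cpa3, Tox and Ikzf2 were higher in EILP than in CLP. NK cells in the EILP pool are argued against, since 21 NK genes give a median NK share of 1.42% (from -1.70% to 19.5%, 17 of 21 above CLP), while Ikzf2 would need 87.0% and Cpa3 and Tox lie above NK itself. The upward shift of the NK list and the rise of Klrk1, which would need 2.38%, are not argued against by these shares, so NK cells in the pool stay open for them as untested. More CMP or LMPP cells in the EILP pool are argued against for Tox, which was 0.70 above the highest of HSC, LMPP and both CMP populations. For Cpa3 and Ikzf2 the smallest shares needed are 60.1% and 29.6%, against a highest median share of 3.76% given by 8 other genes at least 4-fold above CLP in all 4 of these populations. A difference between the cell types may account for these genes, as a hypothesis. The spread of a single array stays open for the number of higher genes, 9 against up to 15 in 1 direction between replicates. The 72 lower ones are above those 15. Replicates of the other populations, compared 1 array against 1, cannot show how far the lone EILP array varies. Its spread is therefore not excluded for the lower genes either.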
